A study of Mus musculus with 236 samples.

How the data were processed

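Single-cell chromatin contacts and RNA were measured in the same cells with HiRES, a method that reads both from one cell, in a female mouse embryonic stem cell line from a C57BL/6J (B6) mother and a CAST/EiJ (CAST) father. Differentiation was started by withdrawing LIF and the inhibitors of MEK and GSK3, per the labels' protocols. The 236 libraries of 1 to 2 cells each fall into 2 groups, cells taken at day 0.5 and at day 2.5, with the day as given in the deposited cell tables. The labels name no separate cultures, so each group was taken as 1 sample. No p-value or standard error was therefore made from cells, and numbers of genes called higher or lower count genes past a fixed size of change, with no test.

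The deposited expression table holds expected counts of unique molecular identifiers (UMIs) per gene and cell, per the file headers and values, and 11.1% of its values above 0 are fractions. The authors' allele table holds expected counts of the same kind for 1082 chrX genes, split into B6 and CAST. The authors' cell tables give counts of contacts and UMIs per cell, the fraction of contacts between chromosomes, a ratio of Y to X reads, and cell cycle scores and classes. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the use of strand and the rules that kept a cell in each deposited table are not given in the sources used here. Fractional counts were summed as deposited and rounded at random, in proportion to the fraction, only for thinning. UMIs on exons were 26.3% of gene UMIs in day 0.5 and 24.2% in day 2.5 cells, so long genes with unspliced RNA weigh more than in a table of exon counts. The tables also held 1101 columns in the expression table and 893 in the allele table that belong to no sample here, and these were not used.

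Of 471 cells in the metadata, 406 were in the expression table and 308 in the allele table. The metadata give each cell 1 of 3 labels under the header sample, here called batches. What these labels stand for is not given in the sources used here. Batch 1 held only day 0.5 cells, batch 3 only day 2.5 cells and batch 2 both groups. Values within batch 2 are therefore given beside many of those of the X chromosome and of some gene lists. They are summarised for the other lists and genes. Cell names also carry the letters A and B, whose meaning is not given in the sources used here. In the expression table, letter B held 42 day 0.5 and 32 day 2.5 cells, all in batch 2. Letter B is therefore not an independent repeat, and its values for genes with low counts rest on few UMIs. Gene positions came from a RefSeq table of the same build, which placed 76.6% of the 39300 gene names and 97.1% of the UMIs.

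Expression was summed over the cells of a group and given as CPM, counts scaled to the same total in each group, with log2((CPM day 2.5 + 5)/(CPM day 0.5 + 5)) as the change. Intervals are 95%. Those of summed levels, their ratios and shares cover counting error only and are exact Poisson for levels, exact conditional for ratios, Clopper-Pearson for shares and Newcombe for differences of shares. Medians have order-statistic intervals over genes or cells, or the range of the members in lists of under 6. The interval of a ratio of medians divides the opposite bounds of both medians, so it is conservative. For a count of 0 the limit given is 3 counts of the total. Intervals of Spearman's rho across genes came from 10000 resamplings of the genes, and that of the slope between autosomal changes from 1000, although genes are not independent. Among 7716 genes with at least 100 UMIs, the 12 highest and 12 lowest changes that went the same way in both letters were named. The 27 gene lists and this rule were fixed before the data were examined. A list member with at least 20 UMIs was called higher or lower at a CPM ratio of 1.5 or its inverse, in the same direction in both letters, and up to 4 members with the most UMIs are given as examples. A list's median was placed among those of 10000 random lists matched on expression in 20 bins. The ribosomal list took every symbol starting with Rps or Rpl and a digit, which also takes in the kinases Rps6ka5 and Rps6kb1 and pseudogenes.

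A cell was one-sided when at least 80% of its allelic chrX UMIs, without Xist and Tsix, came from 1 parent, among cells with at least 20 such UMIs. Xist classes required a summed value of at least 1 UMI of an allele. Silencing of a gene was the B6 share in cells with CAST Xist minus that in cells with B6 Xist, at a minimum of 30 allelic UMIs in each class. The 8 genes with the largest and the 8 with the smallest differences were named, except 1 that is not reported here. Shares of cells with a UMI were repeated with each cell thinned to 5000 UMIs, which left out 7 cells of each group. Alternatives covered scaling, pseudocount, minimum counts, thresholds, thinning and the letters. Leaving out the chrX gene with the largest fall in CPM, with or without Xist, and use of batch 2 alone, of only the cells of the allele table and of only cells with at least 5000 UMIs were chosen after seeing the data.

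Interval and allele steps were tested on simulated data. Simulated counts were Poisson for summed genes and binomial for alleles, with no further variation between cells or cultures. The coverage below therefore checks the computation and does not measure that variation. For the comparison of day 2.5 with day 0.5 over 7716 genes, intervals held the true ratio for 88.2% of the genes simulated at a ratio of 4 and for 95.8% of unchanged genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.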

Results

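Female hybrid embryonic stem cells were profiled early in random X inactivation, the process by which each female cell silences either of its X chromosomes. The expression table held 201 cells at day 0.5 and 205 cells at day 2.5 after withdrawal of LIF and the inhibitors. Cells had a median of 13670 UMIs at day 0.5 (range 501 to 23213) and 15796 at day 2.5 (range 529 to 29275). Summed UMIs were 2655980 and 3186070, to 6 digits. Within batch 2, which held both groups, medians were 11636 UMIs in 121 day 0.5 cells and 15010.5 UMIs in 122 day 2.5 cells. The labels name no separate cultures and each day was taken as 1 sample, so differences below have no check by named replicate cultures. Each day fell in 2 batches, which may or may not be separate cultures. Xist, described below, was at 32.5 and 48.9 CPM in batches 1 and 2 at day 0.5. It was at 1490 and 1498 CPM in batches 2 and 3 at day 2.5. Intervals of summed levels, their ratios and shares cover counting error only. Those of medians and their ratios reflect the spread over cells or genes.

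To ask how far the cells had left the naive state, expression was compared between the days. Naive pluripotency genes were lower at day 2.5, with all 15 measured members lower and a median log2 change of -2.36. This median lay at percentile 0 of matched random lists and was -2.29 within batch 2. Esrrb, an orphan nuclear receptor of the naive network, went from 339 to 12.4 CPM, a ratio of 0.0366. Zfp42 went from 333 to 18.8 CPM and Nr5a2 from 189 to 9.10 CPM, and Morc1 was 18.1 times as abundant at day 0.5. General pluripotency genes had a median of -0.71, with 9 of 14 members lower and 5 neither. Among these, L1td1 went from 287 to 162 CPM, while Sall4 was at 133 and 127 CPM, Tdgf1 at 218 and 175 CPM and Cdh1 at 355 and 459 CPM.

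Formative and primed pluripotency genes were mostly higher at day 2.5, with 12 of 16 members higher and 3 lower. Their median log2 change was 1.22, at percentile 100, and 1.23 within batch 2. Fgf5, a growth factor of the post-implantation epiblast, went from 3.01 to 121 CPM, a ratio of 40.1 (95% interval 20.1 to 93.5). Dnmt3b, a de novo DNA methyltransferase, went from 544 to 1350 CPM, Lin28b from 208 to 542 CPM and Pim2 from 136 to 422 CPM. Dnmt3a was at 261 and 246 CPM. The 3 lower members, named after their values were seen, were Tcf15, Cdh2, which encodes N-cadherin and went from 77.2 to 31.1 CPM, and Dnmt3l, which went from 167 to 27.9 CPM.

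Markers of other lineages were mostly below the minimum of 20 UMIs or at low levels. Of the primitive streak list, 3 of 14 members were measured, with 2 higher and 1 lower and a median of 0.82 (0.45 within batch 2). Nodal went from 23.3 to 44.9 CPM, Wnt3 from 0.753 to 13.8 CPM, and Eomes was at 4.89 and 2.82 CPM. Eomes rests on 13 and 9 UMIs, and within batch 2 it was at 2.78 and 3.94 CPM. The neuroectoderm list had 4 measured members, 2 higher and 1 lower, and a median of 0.85, with Map2 going from 76.8 to 136 CPM and Sox11 from 39.9 to 79.4 CPM. Of 8 measured primitive endoderm genes, 4 were higher, 2 lower and 2 neither, with a median of 0.86. The higher members were Dab2, Col4a1, Lama1 and Lamb1. Gata4, named after its value was seen, was among those called neither, at 12.8 and 13.5 CPM. Lamb1, a laminin chain, went from 24.3 to 161 CPM, and Sparc went from 68.9 to 28.7 CPM. Trophectoderm genes had a median of -1.72 over 4 members, with Tead4 8.83 times as abundant at day 0.5 and Bmp4 going from 38.8 to 2.82 CPM. The two-cell-like list had 1 measured member, Lmx1a, at 4.14 and 4.71 CPM, and its direction changed with the letters and within batch 2. The feeder fibroblast list had 3 measured members and a median of -0.70, and Fn1, the fibronectin gene, was 5.04 times as abundant at day 0.5.

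LIF-STAT3 targets had a median of -0.84, with 4 of 6 members lower and 2 higher, Tfcp2l1 going from 65.7 to 5.96 CPM and Sgk1 from 60.3 to 168 CPM. MEK-ERK target genes had a median of -0.36 with 3 of 9 lower, and Etv4 went from 160 to 41.4 CPM. Wnt targets had a median of 0.08, with 2 higher and 4 lower of 9, and Lef1 went from 1409 to 712 CPM. Polycomb genes had a median of -0.50, with 6 of 13 lower, among them Jarid2 from 4154 to 1215 CPM and Cbx7 from 611 to 164 CPM, and 1 higher, Ezh1, named after its value was seen. DNA methylation genes had a median of -0.64 (-0.20 in letter B), with 6 of 12 lower and 3 higher. The higher members were Dnmt3b and, named after their values were seen, Tet3, which went from 54.8 to 110.01 CPM, and Mbd2, which went from 39.2 to 62.8 CPM. Tet2, a methylcytosine dioxygenase, went from 437 to 30.1 CPM and Tet1 from 1680 to 606 CPM. The p53 response list had a median of 0.88 (0.65 within batch 2), with 5 of 10 members higher and 1 lower, Gadd45a, named after its value was seen. Trp53inp1 went from 58.9 to 309 CPM, and Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, was 3.42 times as abundant at day 2.5.

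Germline genes had a median of -1.18 over 6 members, with Xlr3a going from 43.9 to 2.82 CPM, although Xlr3a and Xlr3b are near-identical copies and uncertain. Heat shock genes had a median of -0.61 with 4 of 7 lower, and Hsph1 went from 254 to 92.7 CPM. S phase genes had a median of -0.30 with 5 of 20 lower, with Hells at 889 and 694 CPM. G2 and M phase genes had a median of -0.08 with 5 of 20 lower, and Top2a was at 502 and 608 CPM. Glycolysis genes had a median of 0.07, with 2 higher and 3 lower of 16, and Pfkp went from 424 to 55.6 CPM. Cytoskeleton and adhesion genes had a median of -0.37, with 2 higher and 5 lower of 15, and Cnn3 went from 134 to 66.2 CPM. Ribosomal protein genes had a median of -0.40, with 39 of 125 lower and 2 higher, while Rpl3 was at 299 and 302 CPM. Mitochondrial genes had a median of -0.50, with 3 of 9 lower, and mt-Cytb went from 30.5 to 11.9 CPM. Median-ratio scaling moved the median of all 13777 genes from -0.065 to 0.071 on the log2 scale. It turned the medians of the G2 and M phase list, to 0.082, and of the Xist partner list described below, to 0.15. The medians of the feeder fibroblast, Wnt, glycolysis and escape lists also turned under other alternatives. The interval of the median held 0 for 17 of the 27 lists, including these 6 and the formative list (-0.09 to 1.47). Of the others, 1 rested on a single gene, and 9, among them the naive list (-3.78 to -1.74), had medians below 0 with intervals that left it out.

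Several medians moved by over 1.5 times with the cells or the scaling used. In letter B they were 0.18 for the primitive streak, 0.41 for the neuroectoderm, -1.06 for the trophectoderm, 0.54 for the p53 response, -0.17 for the ribosomal protein and -0.19 for the mitochondrial list. Median-ratio scaling gave -0.23 for the MEK-ERK and -0.14 for the S phase list, and thinning -0.34 for the heat shock and -0.17 for the S phase list. A pseudocount of 1 CPM gave 1.33 for the p53 response and -1.37 for the feeder fibroblast list, and the mean over cells -0.27 for the mitochondrial list. With no minimum of UMIs the medians were 0.088 for the primitive streak, 0.085 for the neuroectoderm, 0.17 for the primitive endoderm and X-inactivation centre, and -0.0085 for the trophectoderm. They were -0.38 for the LIF-STAT3, -0.14 for the heat shock, -0.022 for the cytoskeleton, -0.35 for the germline and -0.23 for the ribosomal protein list. With only the cells of the allele table the S phase median was -0.16. Within batch 2, 24 of the 27 list medians and all but 6 of the 124 genes chosen by the naming rules kept their sign, with median differences from all cells of 0.094 and 0.11 in log2. The medians were -0.63 for general pluripotency and -0.65 for the Polycomb list there. The 6 genes were Dnmt3a, Eomes, Lmx1a, Ddx4, Rpl3 and mt-Nd5.

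**Figure D1:**
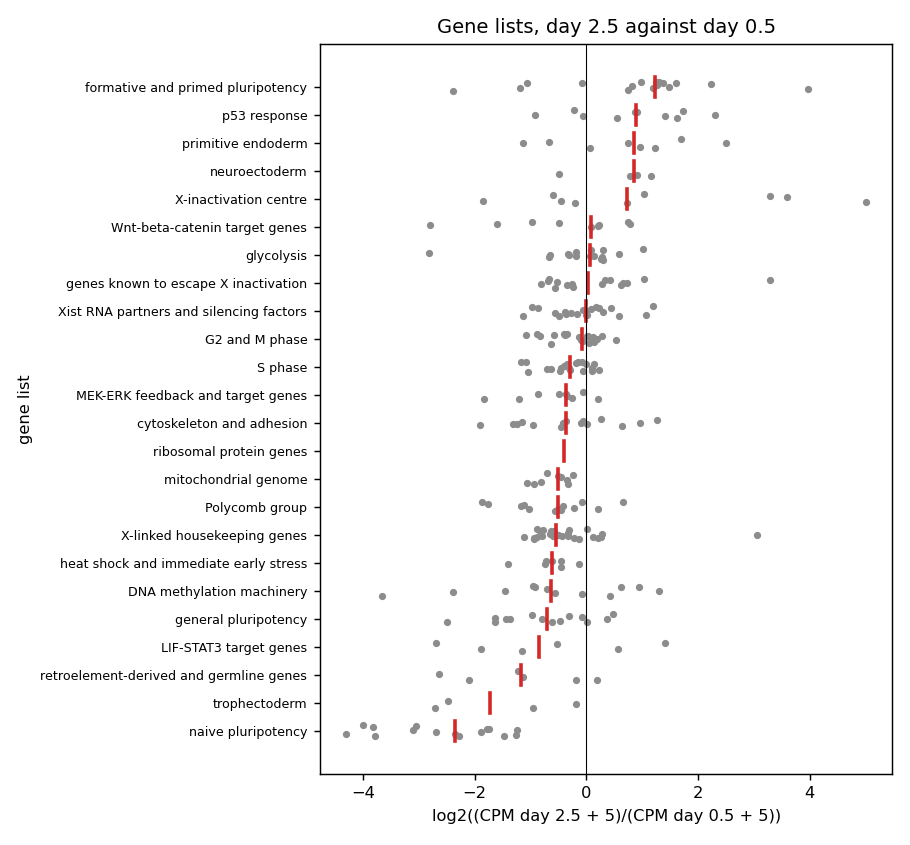
Log2 change in CPM between day 2.5 and day 0.5 for list members with at least 20 UMIs (grey points) and list medians (red bars), with a pseudocount of 5 CPM, for lists with at least 4 measured members. Only the median is drawn for ribosomal protein genes. The naive list has a median of -2.36 and the formative list a median of 1.22.

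Beyond the lists, the gene with the highest change was Sema6a, a semaphorin at 18:47245254-47371200 (GRCm38), which went from 35.4 to 2709 CPM, a ratio of 76.6 (62.5 to 94.8). Zfp608 went from 8.66 to 653 CPM, Pdzrn3 from 22.8 to 759 CPM, Arhgap6 from 14.7 to 534 CPM and Ptprt was 21.8 times as abundant at day 2.5. Cacnb2 went from 24.5 to 510 CPM, Adamts6 from 23.9 to 438 CPM, Gm49685 from 2.45 to 207 CPM, while Kcnj3 had a ratio of 57.7 (24.5 to 179). Has2, which encodes a hyaluronan synthase, had 3 UMIs at day 0.5 and a ratio of 101.4 (34.4 to 494). Xist and Fgf5 were the others of the 12. The lowest change was in Epas1, which encodes a hypoxia-inducible transcription factor and went from 345 to 2.04 CPM. Jam2 went from 421 to 4.08 CPM, Bnc2 from 1532 to 60.7 CPM and Megf11 from 620 to 23.9 CPM. The X-linked 4930519F16Rik, at X:103182978-103256632, went from 5753 to 132 CPM. Gm14820 went from 300.3 to 3.30 CPM, Porcn, which encodes an enzyme that acylates Wnt proteins, from 195 to 5.34 CPM, Dusp27 from 160 to 3.77 CPM, Nrp2 from 182 to 5.02 CPM and Mapt from 349 to 15.4 CPM. Arl14epl had 2 UMIs at day 2.5 and a ratio of 0.0054 (0.00065 to 0.0197). Esrrb was the other of the 12.

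Xist, the noncoding RNA that coats the X chromosome to be silenced (X:103460373-103483233), was 36.1 times as abundant at day 2.5 (29.9 to 43.98). It went from 41.4 CPM (34.04 to 49.9) to 1494 CPM (1452 to 1537). Within batch 2 the levels were 48.9 and 1490 CPM. At day 0.5, 62 of 201 cells had a Xist UMI (30.8%, 24.5 to 37.7), and at day 2.5, 157 of 205 cells did (76.6%, 70.2 to 82.2). Median depths were 13670 and 15796 UMIs, and after thinning to 5000 UMIs the shares were 14.4% and 65.2%. Of 7 markers of other lineages counted beside Xist, Col3a1 was seen in 0 of 201 day 0.5 and 3 of 205 day 2.5 cells, Sox17 in 0 and 2, and 4 others in at most 1 cell of a day, where 0 of 201 allows up to 1.49%. Pax6, also a measured neuroectoderm member and so not a gene known to be absent, was seen in 13 (6.47%) and 6 cells (2.93%). Ftx, a noncoding neighbour of Xist, went from 95.2 to 976 CPM, Jpx from 37.9 to 82.7 CPM and Rlim, which encodes an activator of Xist, from 128 to 213 CPM. Tsix, the antisense partner of Xist, was at 495 and 429 CPM. Its day 2.5 level was 342 CPM in the cells inside the allele table, described below, and 552 CPM in those outside it. The ratio, outside over inside, was 1.61 (1.45 to 1.80). Xist and Tsix overlap and use of strand in counting is not given in the sources used here, so their reads cannot be told apart with certainty. Day 2.5 cells with B6 Xist only had 904 B6 Xist UMIs, with 10 B6 and 89.8 CAST Tsix UMIs. Those with CAST Xist only had 436 CAST Xist UMIs, with 1.5 CAST and 48 B6 Tsix UMIs. Xist reads counted as Tsix would lie on the Xist allele, so this argues against much such counting in these cells. Counting of Tsix reads as Xist was not tested. The X-inactivation centre list had a median of 0.72, with 5 of 9 higher and 2 lower. With only the cells of the allele table, described below, the median was 0.32, the change of Rlim in those cells, which is under the ratio of 1.5 for a higher call. Genes for Xist partners and silencing factors had a median of -0.01, with 3 of 21 higher and 3 lower, Smchd1 going from 276 to 583 CPM and Ncor1 from 1592 to 873 CPM.

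Total output of the X chromosome was lower at day 2.5. Genes of chrX gave 5.56% of nuclear UMIs at day 0.5 and 4.67% at day 2.5, a ratio of 0.840 (0.834 to 0.846), or 5.55% and 4.63% within batch 2. Much of this difference lay in 4930519F16Rik, without which the shares were 5.02% and 4.66%, a ratio of 0.929 (0.922 to 0.936). Without both this gene and Xist the ratio was 0.901. X-linked housekeeping genes had a median of -0.54, with 15 of 28 members lower and 1 higher. Atrx, a chromatin remodeller, went from 2975 to 1900 CPM, while the 1 higher member, Tspan7, named after its value was seen, went from 18.6 to 192 CPM. Genes known to escape X inactivation had a median of 0.02, with 4 of 16 higher and 5 lower, and Kdm6a was at 490 and 621 CPM.

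The chrX allele table held 186 of the 201 day 0.5 cells and 122 of the 205 day 2.5 cells. The 15 day 0.5 cells outside it were all classed as M phase by the authors, but only 7 of the 83 day 2.5 cells were. Those 83 cells had 83.1 CPM of Xist, against 2490 CPM in the 122 cells inside the table, so the allelic values below describe cells with more Xist than the others. One cell with 533 UMIs gave 35 of the 109.5 Xist UMIs of the 83 cells, and without it their level was 56.5 CPM. Their chrX share of UMIs was 5.49%, against 4.09% in the cells inside the table.

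**Figure D2:**
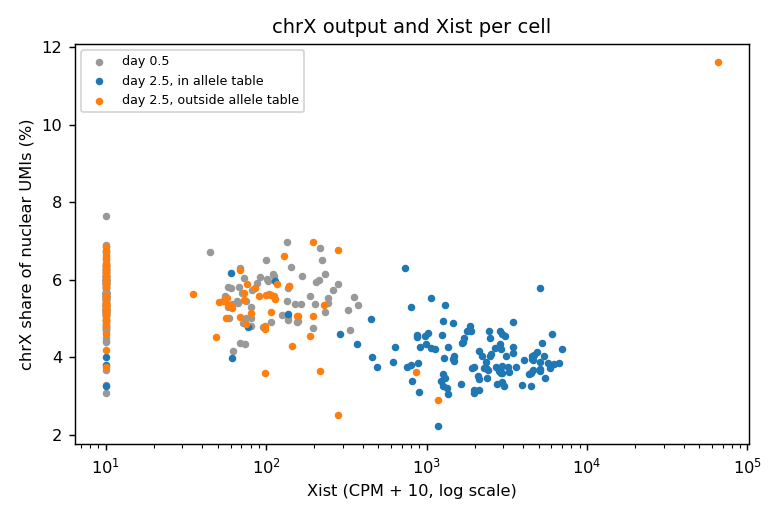
Share of nuclear UMIs from chrX (percent) against Xist (CPM plus 10, log scale) in single cells of day 0.5, of day 2.5 inside the allele table and of day 2.5 outside it. The cell with 533 UMIs stands alone at 11.6%.

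Allelic expression of chrX was balanced at day 0.5 and divided between the parents at day 2.5. The B6 share of allelic chrX UMIs, without Xist and Tsix, was 50.2% (49.8 to 50.5) at day 0.5 and 38.1% (37.6 to 38.6) at day 2.5. Within batch 2 it was 50.4% and 36.1%. The standard deviation over cells was 4.90 percentage points at day 0.5 and 26.6 at day 2.5, where sampling alone would give 2.72 and 3.04. The spread at day 0.5 was thus already wider than sampling alone would give. Intervals of summed allelic shares and of their differences, here and below, do not cover this spread over cells. No cell of 186 was one-sided at day 0.5, which allows a share of up to 1.61%, and 54 of 121 were at day 2.5 (44.6%, 35.6 to 53.9). Within batch 2, 34 of 71 were. The day 2.5 share depended on the threshold of 80%, with 3.31% at 90% and 82.6% at 70%, and was 28.9% after correction for the group mean. After thinning to 20 UMIs, 2.69% of day 0.5 cells were one-sided. Of the 54 cells, 36 drew on the CAST and 18 on the B6 chromosome.

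Xist came mostly from the B6 allele at day 2.5. Of 122 cells, 46 had Xist UMIs of B6 only, 18 of CAST only, 49 of both and 9 of neither. The minor allele had 1 UMI in 31 of the 49 cells, and 18 cells had both at a minimum of 2 UMIs and 5 at a minor share of 20%. Among cells with a single allele, 46 of 64 carried B6 Xist (71.9%, 59.2 to 82.4), or 27 of 37 within batch 2. At day 0.5, 17 cells had B6 Xist, 21 had CAST Xist, 4 had both and 144 had neither. In day 2.5 cells with B6 Xist, 77.1% of chrX UMIs came from CAST (76.3 to 77.8), and in cells with CAST Xist, 77.8% came from B6 (76.6 to 78.9). Their mean was 77.4% (76.8 to 78.1), or 78.3% within batch 2, against 48.3% at day 0.5. In the 9 cells with no allelic Xist UMI the B6 share was 49.9% (48.03 to 51.8).

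**Figure D3:**
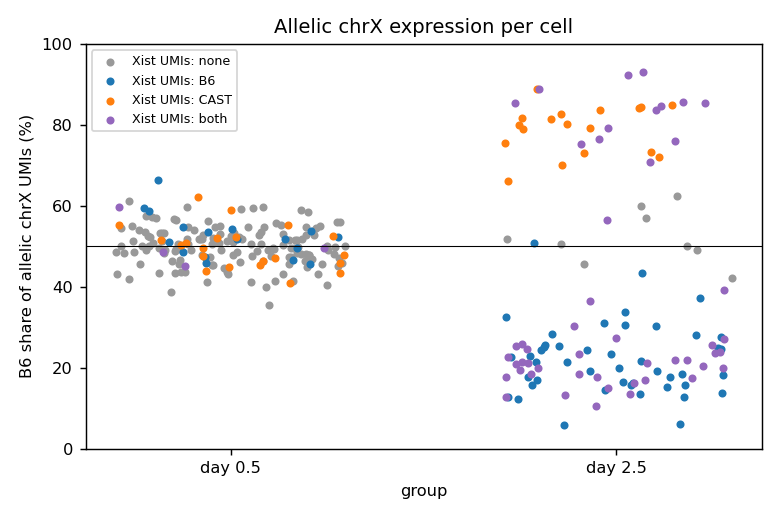
B6 share of allelic chrX UMIs (percent) in each cell of day 0.5 and day 2.5, coloured by the alleles of its Xist UMIs. Day 0.5 cells lie between 35.5% and 66.4%, and day 2.5 cells between 5.77% and 93.04%.

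Silencing differed between genes. Over 47 genes the median difference in B6 share between CAST-Xist and B6-Xist cells was 56.3 percentage points (45.5 to 69.4), and for 45 of them the interval lay above 0. Within batch 2 only 15 genes reached the minimum. Among the largest differences were those in Hs6st2 (95.5 points), Firre (90.9), Eda (90.7), Gm26992, Hdac8 (87.7), Ctps2 (85.4) and Gpc4 (81.4). Gm26992 was at 423 and 343 CPM at both days, beside 495 and 429 CPM of Tsix, and its reads may be shared with Tsix, so its value is uncertain. The smallest were in 5530601H04Rik (7.67 points, -12.3 to 26.3), Ftx (7.67, -0.81 to 16.2), Kdm6a, a histone demethylase gene (10.5, 0.20 to 20.4), Taf1 (20.4), Klhl13, Arhgap6 (26.4), Med14 and Mid1 (35.8). The difference joins both chromosomes, so a small one need not mean little silencing of each copy. In Klhl13 the B6 share was 12.6% in B6-Xist and 34.6% in CAST-Xist cells, against 45.4% at day 0.5. In Taf1 these shares were 21.6%, 42.1% and 38.6%. Of the escape list, Kdm5c had a difference of 35.8 points and Shroom4 of 55.3 points. The median was 20.4 points over the 7 escape list genes and 64.9 points over the other 40.

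**Figure D4:**
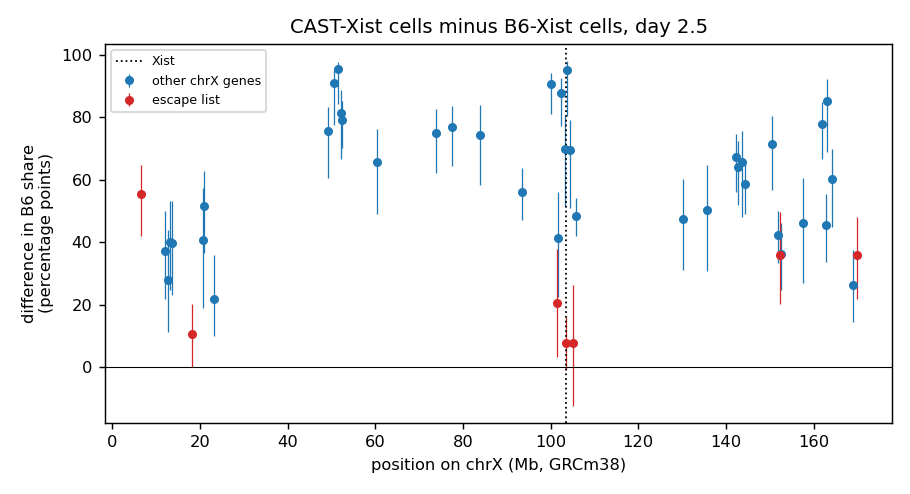
Difference in B6 share (percentage points, with 95% Newcombe intervals) between CAST-Xist and B6-Xist cells of day 2.5, by position on chrX (Mb, GRCm38), with escape list genes in red and Xist as a dotted line. Ftx, beside Xist, lies at 7.67 points.

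Compared between the days over all cells of the allele table, 127 chrX genes had 50 allelic UMIs in each group. The B6 share was lower at day 2.5 by the most in Shroom4, from 72.6% to 34.6%, Klhl13, from 45.4% to 16.2%, Ofd1, from 65.6% to 38.03%, Fgd1, from 55.9% to 28.9%, and Rp2, from 60.2% to 33.3%. It was higher by the most in Xist, from 39.5% to 68.6%, Mid1, from 26.2% to 48.1%, Nhs, from 15.7% to 30.5%, Rbm10, from 46.8% to 56.97%, and Atp6ap2, from 31.5% to 38.2%. These shares pool cells of all Xist classes, in which B6-Xist cells outnumbered CAST-Xist cells. In Klhl13, 420 allelic UMIs came from B6-Xist cells, at 12.6% B6, and 52 from CAST-Xist cells, at 34.6% B6. The interval of the difference in Atp6ap2 ran from -5.57 to 19.1 points. No values within batch 2 are given for these shares. The total level of Mid1 at day 0.5 was 171 CPM in batch 1 and 401 CPM in batch 2. Its log2 change in CPM was 0.61 over all cells and 0.12 within batch 2.

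The authors' cell tables gave fewer contacts at day 2.5, over all 231 day 2.5 and 240 day 0.5 cells of the metadata. The median was 143369 per cell against 183424 at day 0.5, a ratio of 0.782 (0.715 to 0.822). Within batch 2 the medians were 162627 and 188056, and batch 3 had 119380. Sequenced reads per cell, in the deposited unit, had medians of 2.17 at day 2.5 and 2.32 at day 0.5. Within batch 2 they were 2.31 and 2.32, and batch 3 had 2.00. Whether sequencing depth accounts for the contacts was not tested. Contacts between chromosomes made up a median of 8.79% at day 2.5 and 7.44% at day 0.5, a ratio of 1.18 (1.06 to 1.34), or 9.41% and 7.73% within batch 2. By the authors' cell cycle classes, 41 of 201 cells were in G1 at day 0.5 (20.4%, 15.1 to 26.6) and 82 of 205 at day 2.5 (40.0%, 33.2 to 47.1), or 24 of 121 and 46 of 122 within batch 2.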

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

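No paired analysis was possible because each group is 1 sample and the numbers only name libraries. Of the alternatives to the main values, 74 lay within the main interval, 35 moved and 0 changed direction. For single genes 1070 stayed, 166 moved and 4 changed direction, and for the other gene lists 254, 18 and 3. A direction was counted as changed only where the main interval left out no change. Where the interval held it, signs turned in 26 values of 16 genes, among them Dnmt3a (0.18 in letter B), Eomes (0.20 in batch 2) and Ddx4 (-1.50 in letter B), and in 13 values of 6 lists. These were the feeder fibroblast (0.016 in letter B), Wnt (-0.0025 with only the cells of the allele table), escape (-0.28 in letter B), glycolysis (-0.025 in batch 2), G2 and M phase (0.082) and Xist partner lists (0.15), the last 2 with median-ratio scaling. The settings without 4930519F16Rik, with batch 2 alone, with only the cells of the allele table and with at least 5000 UMIs were chosen after seeing the data. The cause was not tested unless given.

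With only the cells of the allele table, the Xist ratio was 63.4, the share of day 2.5 cells with Xist 95.1% and the ratio of chrX output 0.733, since that table leaves out cells with little Xist. The share of cells with Xist at day 0.5 and day 2.5 was 14.4% and 63.9% at 2 UMIs, 1.49% and 54.6% at 5 UMIs, and 14.4% and 65.2% after thinning. In letter B the day 0.5 share was 23.8%. The ratio of chrX shares of nuclear UMIs, the measure of X to autosome output, was 0.850 in letter A, 0.761 in letter B, 0.815 without Xist, 0.929 without 4930519F16Rik, 0.901 without both, 0.818 as a median over cells and 0.911 without the 20 most abundant genes of each kind. The B6 share at day 0.5 was 50.8% in letter B and 51.2% as a median over genes. At day 2.5 it was 39.6% in letter B, 40.5% with Xist and Tsix, 37.5% without the escape and centre lists, 36.1% in batch 2 and 25.4% as a median over cells.

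One-sided cells at day 2.5 were 54.5% in letter B, 3.31% at a threshold of 90%, 82.6% at 70% and 28.9% after correction for the group mean, and 2.69% of day 0.5 cells were one-sided after thinning to 20 UMIs. The chrX share from the chromosome without Xist was 79.1% in letter B, 78.3% at 2 Xist UMIs, 79.3% as a median over cells, 79.7% without the escape and centre lists and 78.3% in batch 2. The ratio of contacts was 0.782, and 0.865 in batch 2. No gene reached the silencing minimum in letter B, and the day 0.5 median of Xist CPM over cells was 0, which allows no ratio. By this count, directions changed for the list median, two-cell-like state, which rests on 1 gene and so has no spread of its own (-0.064 in letter A, -0.41 in batch 2, -0.032 with no minimum of UMIs), and in letter B for Spred1 (0.55), Ogt (-0.031), Actn1 (-0.42) and Thy1 (0.016). Thy1 had 15 UMIs at day 0.5 and 5 at day 2.5 over all cells, so its letter B value rests on very few. The letter B median of the feeder fibroblast list is this same value. Depth limits the silencing of single genes, since 15 genes reached the minimum in batch 2.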

Other observations

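The tests in this part were chosen after the results were seen, except those on chromatin contacts, on misassigned UMIs and on silencing by expression level, and the values by batch and the intervals of rho were added after them. Ftx was nearly as abundant in the day 2.5 cells outside the allele table (990 CPM) as in those inside it (966 CPM), against 95.2 CPM at day 0.5, while Xist was at 83.1 and 2490 CPM. Rlim was at 300 CPM outside the table and 152 CPM inside it. Over 7151 autosomal genes the median log2 difference between these cells was -0.021. Over 309 chrX genes without Xist it was 0.50.

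Day 2.5 cells outside the allele table had little Xist. Lower RNA depth is argued against by a ratio of median UMIs, outside over inside, of 1.03 (0.93 to 1.20; 1.05 and 1.11 within batches 2 and 3), fewer contacts by a ratio of 1.02 (0.901 to 1.25; 1.14 and 1.09), and loss of an X chromosome as the whole cause by a chrX share 1.34 times (1.33 to 1.36) that of the cells inside. Less advanced differentiation may contribute and stays open, since the formative list had a median log2 of -0.28 (-0.69 to 0.06), at percentile 0.07 of matched lists, while the changes from day 0.5 over 7151 autosomal genes were of nearly equal size, with a slope of 0.985 (0.976 to 0.994), outside on inside, or 0.95 with other day 0.5 cells on each side. The naive list alone, at -0.076, would have argued against it, but its genes are near the floor at day 2.5, and the formative list was added for that reason after both values were seen. Thinned to 5000 UMIs, 22.8% of these cells (14.1 to 33.6) and 14.4% of day 0.5 cells (9.81 to 20.2) had a Xist UMI, a difference not detectable at this depth; the unthinned shares, 49.4% (38.2 to 60.6) and 30.8% (24.5 to 37.7), did differ, and the thinned ones were preferred only after both were seen.

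More day 2.5 cells carried B6 than CAST Xist. The B6 share of 50.2% at day 0.5, without Xist and Tsix, argues against an assignment of chrX reads that favours CAST in all cells. Such an assignment would not add B6 Xist calls, so this value cannot explain or exclude a cause of the Xist classes. Undercounting of CAST Xist was not decided by Xist UMIs per cell. Their ratio, CAST-only over B6-only cells, was 1.23 (1.1 to 1.38) over all cells, but 1.74 (1.49 to 2.03) in batch 2 and 0.787 (0.652 to 0.945) in batch 3. These rest on 18 and 46 cells in all, 10 and 27 in batch 2 and 8 and 19 in batch 3. The intervals cover counting error of UMIs only and not the spread over cells. The opposite directions of the batches are therefore not established. Undercounting of CAST Xist as the whole cause is argued against by chrX UMIs without Xist and Tsix. At day 2.5 these came mostly from CAST in 83 cells and mostly from B6 in 38. At day 0.5 the counts were 90 and 95 cells. The selection of cells in the allele table stays open, since the alleles of the other 83 cells were not analysed here. No biological explanation was tested.

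Of day 2.5 cells with at least 10 Xist UMIs, 41 of 85 had UMIs of both alleles. A constant rate of minor-allele UMIs, set to the pooled minor share of 2.36% in the same cells, gave 44.4 cells on average (36 to 53). The observed count lay within this range. Because the rate was taken from these cells, the match shows only that no uneven spread over cells was seen. Misassignment stays a candidate source of the minor allele, not told apart from others. Of all 49 day 2.5 cells with both alleles, 48 had unequal Xist UMIs. In these 48, a median of 79.1% (76.5 to 82.2) of chrX UMIs came from the chromosome of the minor Xist allele. This argues against silencing of both X chromosomes to a like degree in most of these cells. The minor allele had 1 UMI in 31 of the 49 and a share of at least 20% in 5, so the median cannot decide for those 5.

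As a hypothesis, silencing may fall with distance from Xist. Across 46 genes, which are not independent replicates, Spearman's rho was -0.26 (95% interval over resampled genes -0.55 to 0.064), and -0.44 (-0.69 to -0.11) without the escape list, a choice made after seeing the data. A second hypothesis, that genes more expressed at day 0.5 are silenced less, gave a rho of -0.10 (-0.39 to 0.20) across 47 genes and -0.19 (-0.49 to 0.14) without the escape list. Both stay open, since each interval over all genes holds the bound of -0.2.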
